A study of Homo sapiens with 36 samples.

How the data were processed

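Total RNA of human fibroblasts was measured on 36 arrays. The authors deposited 1 linear intensity per probe set and array, and the software that summarised the probes is not given in the sources used here. The deposited intensities had a 2% trimmed mean between 800.2 and 800.4 on every array, so each array had been scaled as a whole, while array medians ran from 234.5 to 374.8 and the distributions differed. Arrays were grouped by the words healthy and injured in their labels, 18 each. The labels also carry a code of a number and a letter whose meaning they do not give; 12 codes occur in both groups.

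Of 12558 probe sets that are not array controls, 10943 had 1 gene symbol in the platform annotation, 545 had several and 1070 had none; symbols came from that annotation and an updated gene table, and no gene was named from a probe set with several. The 67 control probe sets and 28 probe sets of XIST and Y-linked genes were left out of the tests. Intensities were quantile normalized over all arrays and transformed to log2(intensity + 16). The 40% of probe sets with the lowest mean over all arrays were left out, which left 7518. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it.

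Groups were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block was used. Gene lists, 31 fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives; a list needed 4 measured members, which 29 had. The genes named were the 12 highest and the 12 lowest differences among genes past the threshold with 1 symbol, the 4 members with the smallest p of each called list and the 2 with the smallest p of each other list. Other members were named after their values were seen. COL1A1, PRDX6, SMAD7 and PPP1R15A were the exception in a count, and CFD and LIPE marked the range of an untested list. DPT, PRRX1 and PDGFRA showed the spread of the fibroblast markers. FTL and HMOX1 had the largest differences of the NRF2 list, and NFE2L2 encodes NRF2. The 3'/5' control ratio was compared by a permutation test with 100000 resamples. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

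The fit was tested on simulated data of 7518 probe sets for the injured against healthy comparison. It recovered 44.8% of probe sets changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 98.5% of those changed by 2; 9 of 174 calls were of unchanged probe sets, and 0 of 100 unchanged lists were called. Simulated probe sets and simulated arrays varied independently, so that test covers neither correlated lists nor correlated arrays. In the real data, deviations of arrays that share a number within a group correlated at 0.274.

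Alternatives covered the normalization, the pseudocount (1 and 64), the filter, the code as a replicate block, its number as a random block or averaged, its letter, the 3'/5' ratio as a covariate, array weights, the variance model and leaving out each array in turn. With the random block, lists were tested on the moderated statistics. A further pair of alternatives, without 2 arrays that stood apart and without probe sets with a within-group SD over 1.5, was chosen after seeing the data.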

Results

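In a series titled for macular degeneration, a disease of the retina, messenger RNA of human fibroblasts was measured on 36 single-colour oligonucleotide arrays, 18 labelled healthy and 18 labelled injured. Each array gave 1 linear intensity per probe set, a group of short probes summarised as 1 value, and 12558 probe sets were not array controls. The labels do not state whether healthy refers to uninjured cells or to healthy donors, or what the injury was in each culture. They also do not state whether the arrays came from separate cultures or donors, so the p-values rest only on the spread between these arrays. The fit treated the arrays as independent. Deviations of arrays that share a number within a group correlated at 0.274, against -0.07 for other pairs, and the p-values do not allow for that. The deposited intensities had a 2% trimmed mean between 800.2 and 800.4 on each array, and array medians lay between 234.5 and 374.8. Differences below are injured minus healthy on the log2(intensity + 16) scale after quantile normalization, which understates changes of dim transcripts, and the number of arrays limits their precision.

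The comparison asked which transcripts differed between arrays labelled injured and arrays labelled healthy. Among genes past the threshold, with the brightest probe set standing for each gene, the 2 largest rises were of MMP1 and MMP3, which encode matrix-degrading enzymes. MMP1, interstitial collagenase, had a mean of 12.94 ± 1.09 (SD, n = 18) in injured arrays against 9.45 ± 1.45 in healthy arrays, 11.2-fold higher, and all 18 injured arrays lay above the healthy mean (adjusted p = 6.1e-07). MMP3, stromelysin, rose by 3.08 ± 0.54 (SE), 8.46-fold (adjusted p = 2.1e-04). The neutrophil chemokine CXCL8 rose by 2.79 ± 0.80 (adjusted p = 0.0146), and its other probe set by 1.87 ± 0.47 (adjusted p = 0.005). CXCL3, a related chemokine, rose by 1.47 ± 0.42 (adjusted p = 0.0147). HSPA6, an inducible heat shock protein, rose by 2.56 ± 0.54, with 16 of 18 injured arrays above the healthy mean. Thrombomodulin, THBD, rose by 2.08 ± 0.33, and HAS2, which makes hyaluronan, by 1.48 ± 0.41. The others among the 12 highest were UCHL1, RGS2, TIPARP, STC1 and IL13RA2, with differences between 1.38 and 1.42. IL13RA2 was close to the threshold (adjusted p = 0.0478) and lost its call when any of 24 single arrays was left out. Among the 19 arrays of letter a alone, CXCL8, CXCL3, HSPA6, HAS2, UCHL1, STC1 and IL13RA2 did not pass (adjusted p from 0.0973 to 0.272); over all alternatives the call ended in 7 of 18 for IL13RA2, 5 of 19 for UCHL1, 4 of 19 for STC1, 4 of 18 for HAS2, 3 of 18 for CXCL8, 2 of 18 for CXCL3 and 1 of 17 for HSPA6, and in 0 for MMP1, MMP3, THBD, RGS2 and TIPARP.

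The injured arrays were not alike. On the first principal component, which held 15.6% of the variance, healthy arrays lay between -20.25 and -2.71 and injured arrays between -13.05 and 44.32, with 13 of 18 injured arrays above every healthy array and 5 inside the healthy range. On the second, with 13.3% of the variance, injured 14a, 15a and 16a lay at 44.94, 47.43 and 59.27, and every other array at 11.13 or lower. The numbers 15 and 16 occur in injured arrays only. Inside the healthy range of the gene itself lay 3 injured arrays for MMP1, 15 for MMP3 and 15 for CXCL8. The same healthy array held the highest healthy value of each gene, at 12.53, 12.71 and 12.55. The next healthy values were 11.29, 10.01 and 11.75, so the counts for MMP3 and CXCL8 depend on that array. The same 3 arrays, 4c, 5a and 5b, were the lowest injured arrays for each of these genes, and 5a and 5b share a number.

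**Figure D1:**
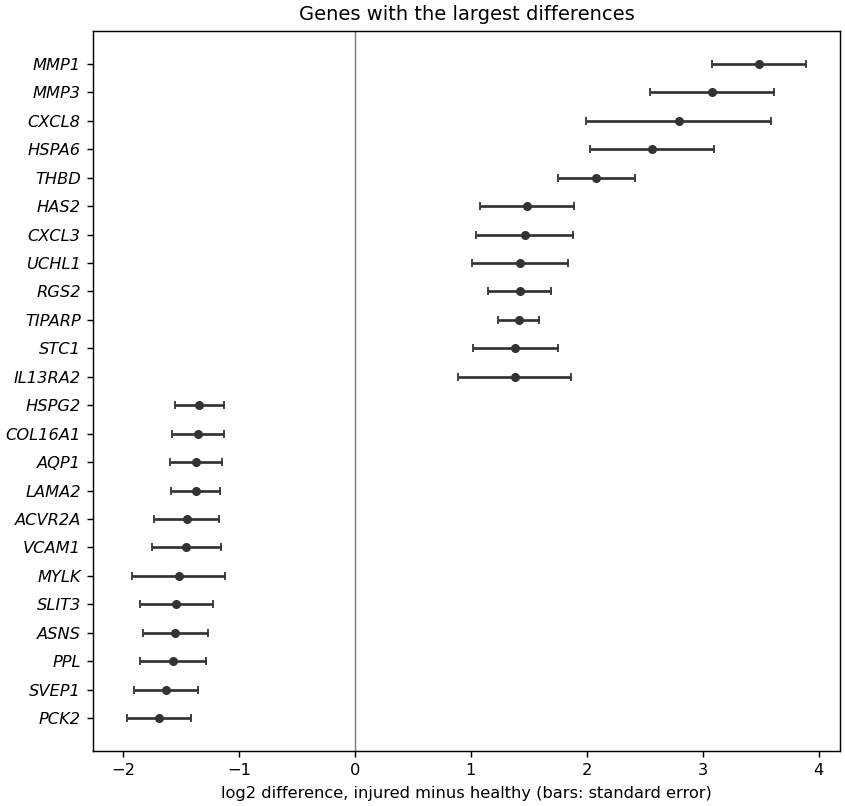
The horizontal axis gives the log2 difference, injured minus healthy, for the 12 genes with the largest positive and the 12 with the largest negative difference past adjusted p 0.05, with 18 arrays per group. Points are fitted differences and bars are standard errors; MMP1 stands highest at 3.49 and PCK2 lowest at -1.69.

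Among genes past the threshold, each read by its brightest probe set, PCK2 had the lowest difference. This gene, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 1.69 on the log2 scale (SE 0.28, adjusted p = 8.82e-05), and ASNS, asparagine synthetase, fell by 1.55 (SE 0.28, adjusted p = 2.99e-04). The adhesion molecule VCAM1 fell by 1.45, and all 18 injured arrays lay below its healthy mean. SVEP1, PPL, SLIT3, MYLK, ACVR2A and the water channel AQP1 had differences between -1.63 and -1.37. The matrix genes LAMA2, COL16A1 and HSPG2 completed the 12 lowest, at -1.38, -1.35 and -1.34. The call of MYLK ended in 4 of 19 alternatives and that of SLIT3 in 1, among arrays of letter a (adjusted p = 0.0575).

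**Figure D2:**
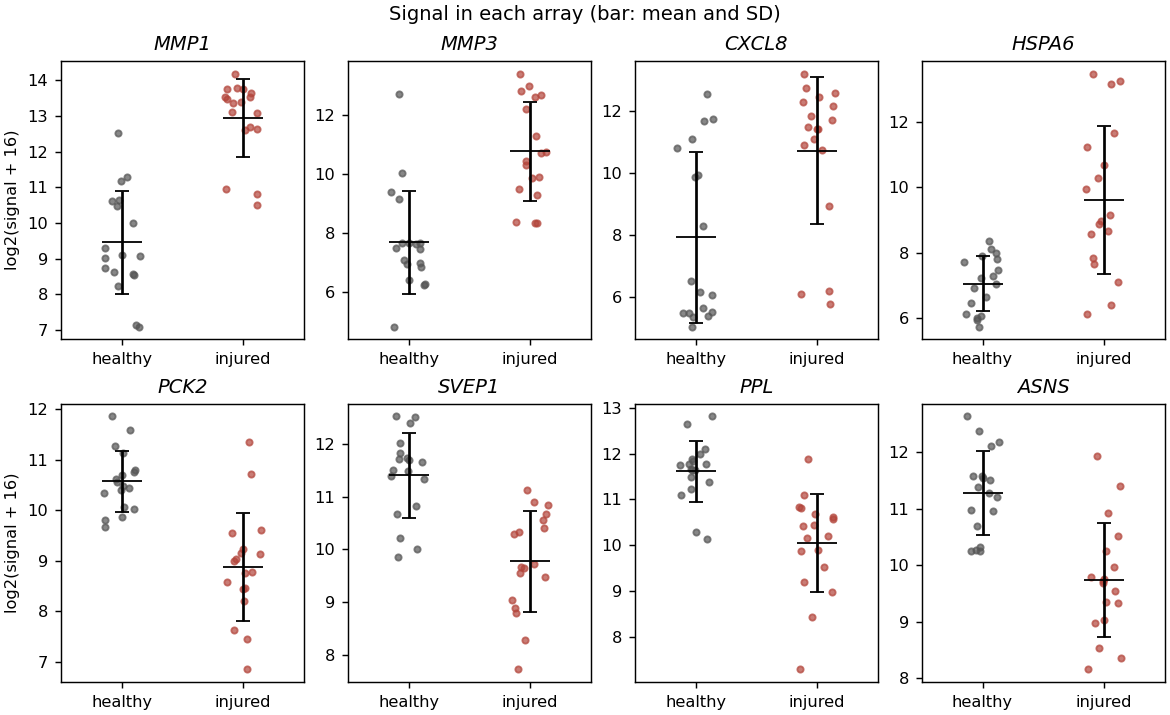
Each point is 1 array and its log2(signal + 16), the vertical axis, for the 4 highest and 4 lowest genes by difference among those past adjusted p 0.05, in the healthy and injured groups of 18 arrays; bars show the mean and SD. MMP1 averaged 9.45 in healthy and 12.94 in injured arrays, CXCL8 spread widely in healthy and injured arrays, with SDs of 2.75 and 2.36, and HSPA6 had SDs of 0.84 and 2.27.

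In all, limma called 1124 of 7518 tested probe sets at an adjusted p of 0.05, 578 higher and 546 lower in injured arrays. With 1 probe set per gene, 856 of 5446 genes passed, 438 higher and 418 lower. Changes of 1 or more on the log2 scale were found for 34 genes that rose and 60 that fell. Of 154 called genes with 2 or more probe sets, 137 had every probe set in the same direction. The same direction did not always mean a further call. For PSMA2 another probe set was at 0.24 and did not pass (adjusted p = 0.421), nor did 1 of E2F1 at -0.18 (adjusted p = 0.612). The same held for 1 of MSMO1 at -0.44 (adjusted p = 0.129) and 1 of MXI1 at 0.53 (adjusted p = 0.082).

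Among 52 measured genes of fibrillar collagens and other matrix proteins, 22 fell and 0 rose, with a list median of -0.59 (camera adjusted p = 6.19e-13; adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone, 32 fell and 1 rose, COL1A1, which did not pass over all probe sets (2.02 ± 0.90 SE, adjusted p = 0.127). Its probe set had within-group SDs of 2.93 and 2.87, and the gene's other probe set differed by -0.115 (adjusted p = 0.800). LOXL1, an enzyme that crosslinks elastin, fell by 1.17 (SE 0.14, adjusted p = 1.06e-06), and all 18 injured arrays lay below every healthy array. FBN1, fibrillin-1 of the elastic microfibril, fell by 1.24 (SE 0.20). The list of myofibroblast and TGF-beta targets had 9 of 33 members lower and 1 higher, SMAD7, with a median of -0.39 (camera adjusted p = 1.37e-04; adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone, 13 fell and 1 rose. Its leading members were PDLIM7 at -0.79, CDH11 at -0.78 and LMOD1 at -1.04. The list of matrix proteases and inhibitors, which holds MMP1 and MMP3, had 4 members higher and 4 lower of 27 and was not called (adjusted p = 0.798); adjusted over the list alone, 4 rose and 6 fell.

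The proteasome, heat shock and NRF2 lists were called higher. Of 33 proteasome genes 14 rose and 0 fell, with a median of 0.34 (camera adjusted p = 7.01e-10; adjusted p = 0.125 with an estimated correlation), and 22 rose when adjusted over the list alone. PSMC1 rose by 0.72 ± 0.14 (SE), PSMB5 by 0.46, PSMA2 by 0.50 and PSMA3 by 0.55. Of 23 heat shock and chaperone genes 10 rose and 0 fell (median 0.38, camera adjusted p = 8.55e-06; adjusted p = 0.234 with an estimated correlation), and 13 rose and 1 fell when adjusted over the list alone. HSPE1, the mitochondrial co-chaperonin, rose by 1.02 ± 0.19, FKBP4 by 0.95 and DNAJA1 by 0.85. The list of oxidative stress and glutathione genes is named for targets of the transcription factor NRF2 and also holds its own gene, NFE2L2. Of its 27 genes 10 rose and 1, PRDX6, fell (median 0.33, camera adjusted p = 1.37e-04, or 0.125 with an estimated correlation). Adjusted over the list alone, 11 rose and 2 fell. The largest differences in the list, FTL at -1.88 and HMOX1 at 1.67, did not pass over all probe sets (adjusted p = 0.094 and 0.066). Thioredoxin, TXN, rose by 0.73 ± 0.11, NQO1 by 0.72, GSR by 1.06 and PRDX1 by 0.46.

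Genes of the ER stress and amino acid response fell, 12 of 28 with 1 higher, PPP1R15A (median -0.37, camera adjusted p = 1.37e-04; adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone, 14 fell and 4 rose. WARS1, a tryptophanyl-tRNA synthetase, fell by 0.77 (SE 0.13), PHGDH, of serine synthesis, fell by 0.63 and PDIA6 fell by 0.55. Of 19 cholesterol and fatty acid synthesis genes 4 fell and 1 rose (camera adjusted p = 0.025; adjusted p = 0.405 with an estimated correlation); adjusted over the list alone, 5 fell and 1 rose. SREBF2, a regulator of sterol synthesis, fell by 1.02 (SE 0.15), and all 18 injured arrays lay below its healthy mean. LSS fell by 0.60, MSMO1 fell by 0.62, and ELOVL5 rose by 0.38. Of 42 cell cycle genes 3 fell, TK1 at -0.78, E2F1 at -0.43 and UBE2C at -1.04, and HMGB2 rose by 0.50; the list was called lower (camera adjusted p = 0.0049; adjusted p = 0.835 with an estimated correlation) but not by fry (adjusted p = 0.242), with 2 lower and 1 higher when adjusted over the list alone. UBE2C lost its call without any of 25 single arrays. The list of apoptosis regulators was called higher (camera adjusted p = 0.0312; adjusted p = 0.234 with an estimated correlation), but 1 of its 21 members passed, BNIP3, at 0.57, and 0 passed when adjusted over the list alone; MCL1 at 0.37, CYCS at 0.40 and BNIP3L at 0.41 did not pass. BNIP3 lost its call without any of 18 single arrays, and the list without any of 3. Over 21 alternatives the call ended in 7 for the cholesterol list, 7 for the apoptosis list and 5 for the cell cycle list, and in 1, the estimated correlation, for each of the other 6 called lists.

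**Figure D3:**
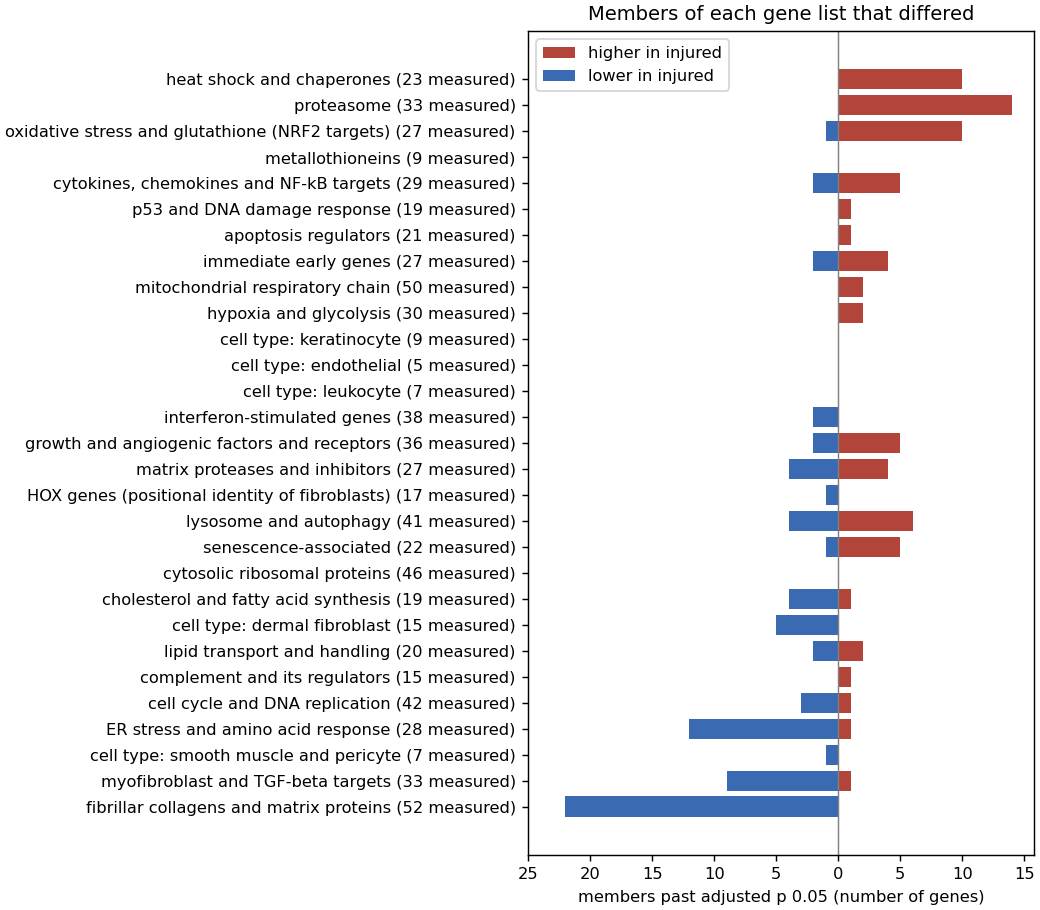
The horizontal axis counts the members of each of 29 gene lists that passed adjusted p 0.05, higher in injured arrays to the right and lower to the left, with the number of measured members beside each name. Lists are ordered by their median difference; 22 of 52 matrix protein genes lay to the left and 14 of 33 proteasome genes to the right.

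The 20 other tested lists were not called by camera, though single members passed. PLIN2, which coats lipid droplets, rose by 0.98 ± 0.11 (SE) and LRP1 fell by 0.94 in the list of lipid transport (2 higher, 2 lower of 20; adjusted p = 0.459). GLA rose by 1.19 ± 0.19 and the protease CTSL by 0.78 in the list of lysosome and autophagy (6 higher, 4 lower of 41; adjusted p = 0.788). NR4A3 rose by 1.07 and EGR3 fell by 1.23 among immediate early genes (4 higher, 2 lower of 27; adjusted p = 0.459). PTGS2, cyclooxygenase-2, rose by 1.29 while VCAM1 fell among cytokines, chemokines and NF-kB targets (5 higher, 2 lower of 29; adjusted p = 0.385). FGF5 rose by 0.75 and PDGFRB fell by 0.98 among growth and angiogenic factors (5 higher, 2 lower of 36; adjusted p = 0.788). Senescence-associated genes, which include MMP1 and MMP3, had 5 higher and 1 lower of 22, a median of -0.12 and a mean of 0.39 (adjusted p = 0.554). Interferon-stimulated genes had 2 of 38 lower, PML at -0.35 and GBP1 at -0.87 (adjusted p = 0.788). The other PML probe sets, at -0.14, -0.45 and -0.035, did not pass (adjusted p = 0.670, 0.162 and 0.951). For complement, 1 of 15 members rose, THBD, and CD59 at 0.29 did not pass (adjusted p = 0.788). HOXC4 fell by 1.13 and HOXC6 at -0.21 did not pass (1 lower of 17; adjusted p = 0.459). CCNG2 rose by 0.44 and XPC at -0.30 did not pass in the p53 list (1 higher of 19; adjusted p = 0.473). MXI1 and BNIP3 rose by 0.36 and 0.57 in the hypoxia list (2 higher of 30; adjusted p = 0.459), and MXI1 lost its call without any of 15 single arrays. NDUFS1 rose by 0.40 and NDUFAB1 by 0.49 in the respiratory chain list (2 higher of 50; adjusted p = 0.304). No metallothionein passed, with MT2A at 0.41 and MT1F at 0.46 (adjusted p = 0.0854 for the list of 9). No ribosomal protein gene passed, with RPS19 at -0.31 and RPS21 at -0.42 (adjusted p = 0.0552 for the list of 46). Adjusted over the list alone, 7 rose and 7 fell for lysosome and autophagy, 6 rose and 2 fell for immediate early genes and also for cytokines, 5 rose and 2 fell for growth factors, and 5 rose and 1 fell for senescence. By the same count 2 rose and 3 fell for lipid transport, 2 rose for the respiratory chain, 1 rose for complement and 1 fell for the HOX genes. The p53, hypoxia, interferon, metallothionein and ribosomal lists had 0 by that count.

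Of 15 dermal fibroblast markers 5 fell, THY1 by 0.78 and PDGFRB by 0.98 among them, and the list was not called by camera (adjusted p = 0.0536); adjusted over the list alone, 5 fell. Fry, which does not compare a list with other genes, called it lower (adjusted p = 0.0037). Lists for keratinocytes, endothelial cells and leukocytes had 0 members past the threshold, with medians of 0.06, 0.04 and 0.03 and SFN at 0.21, PKP1 at 0.17, FLT1 at 0.30, ENG at -0.17, NKG7 at 0.43 and CD3E at -0.13 (adjusted p = 0.633, 0.788 and 0.788 for the lists). The other probe set of SFN was at -0.03 and that of FLT1 at -0.06. Of 7 smooth muscle and pericyte markers LMOD1 fell, and NOTCH3 at -1.39 did not pass (adjusted p = 0.132); adjusted over the list alone, 2 fell. Melanocyte and adipocyte markers had 3 measured members each and were not tested as lists; their differences ran from -0.46 for CFD to 0.26 for LIPE. The mean log2 ratio of 3' to 5' control probe sets of beta-actin and GAPDH, a sign of RNA integrity, was 0.02 ± 0.42 (SD, n = 18) in healthy and -0.004 ± 0.591 in injured arrays, a difference of -0.03 with an interval of 2 standard errors from -0.37 to 0.32 (two-sided permutation test, p = 0.886).

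The 9 list calls rest on a preset correlation between genes of 0.01, and with an estimated correlation 0 lists passed after adjustment and 6 had an unadjusted p under 0.05. Of 99 other splits of the arrays 19 gave as many lists, so the count of lists could not be told from chance. By a count chosen after seeing the data, with the real split included, 1 of 100 splits gave the proteasome list a p as small, 3 the matrix and ER stress lists, 5 the heat shock, NRF2 and myofibroblast lists and the dermal fibroblast list, which camera did not call, 7 the apoptosis list, 24 the cholesterol list and 39 the cell cycle list.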

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

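The signals here were picked after the values were seen, from probe sets that the comparison left out because they were dim. When the filter was dropped and all probe sets were tested, 142 of 5012 dim probe sets passed adjusted p 0.05, 91 higher and 51 lower in injured arrays. The 5 with the highest fitted difference were ITGA2, a collagen-binding integrin chain, at 2.13 ± 0.38 (SE, adjusted p = 3.43e-04, higher in 15 of 18 injured arrays), MMP10, stromelysin-2, at 2.04 ± 0.35 (adjusted p = 2.53e-04, 15 of 18), BMP2 at 1.77 ± 0.39 (adjusted p = 0.003, 16 of 18), AJAP1 at 1.65 ± 0.34 (adjusted p = 0.002, 18 of 18) and RRAGD at 1.57 ± 0.23 (adjusted p = 2.45e-05, 18 of 18). Healthy means of these genes lay between 4.78 and 6.04 on the log2(intensity + 16) scale, near the lowest signals on the arrays: 1.94% of probe sets had a lower healthy mean than MMP10, 3.48% than BMP2 and at most 18.3% than the others. The differences of MMP10 and BMP2 therefore have no measured size, and the order of the 5 is not measured.

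The tests of fibroblast share, of probe-level behaviour and of RNA integrity for the matrix genes were chosen after related values had been seen. The criteria of the other tests in this part were written after the main fit had been run. Injured arrays spread more widely than healthy arrays: the median ratio of variances was 1.63, and 76.3% of probe sets had the higher variance in injured arrays. Relabelling the deviations gave a ratio as far from 1 with p = 0.0057, and with p = 0.0051 when arrays of the same group and number moved together (two-sided permutation tests, 100000 resamples each). With the 3'/5' ratio as a covariate within groups the ratio was 1.55 (1.46 to 1.68 with each array left out), and after averaging arrays of the same group and number it was 1.86 (1.62 to 2.09). As far as the 3'/5' ratio measures RNA integrity, that argues against RNA integrity and repeated numbers as the whole source. The left-out ranges were added after the first results. Injured 14a, 15a and 16a stood apart on the second principal component and carry different numbers. None of these checks shows how much of the wider spread they carry. A variable response to injury may remain, as would unequal handling of the cultures; neither was tested.

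Matrix protein genes were lower in injured arrays, with a list median of -0.59, and of 10000 random lists matched on mean signal 0% had a median as low, the lowest being -0.23. That comparison bears on brightness alone, since the genes of a random list were drawn separately. Members of the matrix list had an estimated correlation of 0.21, and with it camera did not call the list (adjusted p = 0.125). Within groups the list mean had a slope of -0.0011 (SE 0.113) on the 3'/5' ratio, so, as far as this ratio measures RNA integrity, at 2 standard errors the group difference in that ratio allows a shift of at most 0.0833, against a list mean difference of -0.55. The 9 measured fibroblast markers outside the list had a median of -0.064. The standard error of their mean, taken over the 9 genes and not over arrays, was 0.15. PDGFRB was at -0.98, THY1 at -0.78 and DPT at -0.49, against PRRX1 at 0.45 and PDGFRA at 0.17. If the cells in their place lacked both these markers and the matrix transcripts, a lower share of fibroblasts would lower all the markers by about the list median. Other cells were not measured apart. Only under that condition do the markers argue against a lower share as the whole source, and markers that went both ways leave a partial one open. A change in matrix transcription with injury may account for the fall and was not tested apart from the group label, as a hypothesis drawn from the same data.

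Some probe sets swung widely between arrays of the same group, 88 with a within-group SD over 1.5, among them 2.66% of the brightest 5% and 0.984% of the dimmer part below the median. In healthy arrays 1 probe set of COL1A1 ran from 4.05 to 13.16 and the other from 6.77 to 9.17, 1 of B2M from 6.44 to 12.88 and another from 13.63 to 14.04, and 1 of EEF1A1 from 4.73 to 13.38 and another from 13.42 to 14.27; these genes were chosen after their values were seen. Misbehaviour of single probe sets was a candidate explanation. For 33 swinging probe sets another probe set of the gene was tested, and the median correlation with it was 0.86. These correlations ran from -0.32 to 0.98. Where both probe sets of a gene swung, as for HSPA6 and CXCL8, their correlation counted for each. The median was 0.546 for bright steady probe sets, but a wider swing by itself raises such a correlation, so that is no like comparison. The median of 0.86 argues against misbehaviour for the 33 as a set, 23 of these correlations being 0.6 or more and 7 under 0.3. For the 55 swinging probe sets with no other probe set to compare nothing decides. No biological explanation was tested.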

How the results depend on the processing

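The alternatives without arrays that stood apart or swinging probe sets, and the splits that use numbers, were chosen after seeing the data. Other alternatives were fixed before the data were examined. The criterion for the plain splits of the arrays was written after the main fit had been run. The real split was the only 1 of 100 splits of the arrays to give 1124 probe sets, with 157 the highest other. The same held for 100 splits that kept arrays of 1 group and number together, with 206 the highest other. Chance is thus argued against down to 1 in 100, the least that 100 splits can show. Neither set kept numbers balanced between the groups. For the 9 gene lists 20 of 100 splits, the real one included, gave as many, with 13 the highest other. Among the splits by number 15 of 100 did, with 16 the highest other, so chance is not excluded for the lists. Over the 30 arrays whose number occurs in both groups the real labels gave 792 probe sets and 8 lists; of 100 reassignments within numbers, the real one included, 1 gave as many probe sets, with 0 the highest other, and 17 as many lists, with 11 the highest other. Leaving out each of the 36 arrays in turn gave 927 to 1270 probe sets, 473 to 649 higher and 454 to 621 lower, and 8 to 12 lists. Normalization, pseudocount, filter, variance model, weights, the 3'/5' covariate and both added alternatives kept the count within 1.5 times. Without the numbers 7 and 8 there were 607 calls (317 higher, 290 lower) over 26 arrays, and among arrays of letter a 245 (107 higher, 138 lower) over 19; fewer arrays were tested. Of 69 named genes that were called, 29 stayed past the threshold under every alternative that measured them; 37 lost their call among arrays of letter a, 23 over the shared codes with no replicate block, 19 with it and 15 without the numbers 7 and 8, and at most 7 under any setting that used all 36 arrays. Leaving out 1 array ended 4 of these calls, IL13RA2, BNIP3, UBE2C and MXI1. No called list and none of these 69 genes changed direction in these runs. The 3'/5' difference was 0.0135 without quantile normalization, against -0.03, neither past the threshold. Signal near background limits dim probe sets.

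The code did not meet the criterion for pairing set beforehand, that every pair's correlation be over 0.1: 5 of 12 same-code pairs had a correlation of deviations above it, with a range from -0.07 to 0.58, 3 of 12 healthy arrays correlated best with their own code, and sex-linked transcripts disagreed in 3 of 12 pairs. Same-code arrays still correlated by 0.156 more than other pairs across groups (permutation p = 8.00e-04), as did arrays of the same number (permutation p = 1.00e-04, the smallest that 10000 draws can give), with a mean of 0.324 over 5 pairs of other letters and 0.0279 over 7 pairs of letter a. With the code as a replicate block over the shared codes there were 480 calls (264 higher, 216 lower), and over the same 24 arrays without the replicate block 385 (214 higher, 171 lower). Arrays that share a number within a group correlated at 0.274 against -0.07 for other pairs (permutation p = 1.00e-04), so arrays are not all independent. Averaging them gave 951 calls. The number as a random block gave 1573, but it joins arrays across both groups. That count thus also draws on comparison within numbers and is no plain correction for dependence within groups.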

Other observations

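The lists in this part were put together after the values of their genes were seen, so no list test is given. Of 15 measured cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 9 fell and 2 rose (median -0.46). IARS1 fell by 0.81 (SE 0.13), AARS1 fell by 0.82 (SE 0.17) and EPRS1 fell by 0.59 (SE 0.11), each below the healthy mean in 17 of 18 injured arrays, while HARS1 rose by 0.54 (SE 0.17) and KARS1 by 0.34 (SE 0.09). Of 9 polyamine genes ODC1, which makes putrescine, rose by 1.06 ± 0.17 (SE) and SAT1, which acetylates polyamines, by 0.91 ± 0.17.

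Of 6 aryl hydrocarbon receptor targets 3 rose, TIPARP by 1.41, CYP1B1 by 0.92 and NQO1 by 0.72, and CYP1A1 at -0.23 did not pass. The list of MAP kinase feedback genes and ERK targets had 5 of 13 members higher, PHLDA1 by 1.35, DUSP5 by 1.11 and DUSP6 by 0.61 among them, and ETV5 fell by 0.68. Of 16 ubiquitin ligases, conjugases and deubiquitinases 4 rose, UBE2N by 0.71 and CUL1 by 0.34 among them.

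HMOX1, heme oxygenase 1, differed by 1.67 ± 0.63 (SE) and did not pass (adjusted p = 0.066). In the 18 injured arrays its values left a gap: 10 lay between 7.12 and 9.31 and 8 between 12.32 and 13.67, while healthy arrays lay between 5.75 and 10.92. The gap was picked after the values were seen. HMOX1 had no other tested probe set, and the SDs were 1.55 in healthy and 2.38 in injured arrays. Behaviour of that probe set thus could not be told from a difference in the transcript.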
